A study of Mus musculus with 12 samples.

How the data were processed

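RNA of 12 samples was measured on mouse one-colour arrays with biotin-labelled targets, after extraction with Trizol reagent, per the labels. The samples formed 6 groups of 2: HAFTL with beta-estradiol, vehicle C10, and C10 with beta-estradiol for 3, 12, 24 and 48 h. Groups and replicate numbers came from the sample titles. The labels give a time of treatment only for C10 with estradiol, and none for vehicle C10 or HAFTL.

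The deposited values are linear signal intensities per probe set, as their range in the deposited table shows, and no label or header names their scale. Their mean after trimming 2% at each end was equal in all arrays, so the deposited intensities had been scaled between arrays. The summarising and scaling methods are not given in the sources used here, and neither are detection calls. Median intensity per array ranged from 68.5 to 85.0, a range of 0.31 on the log2 scale. Because these medians differed, the rule fixed before the data were examined called for quantile normalisation of the log2 values over all 45101 probe sets. The 64 control probe sets were then left out, and signals under 16 were set to 16. Between 21.2% and 24.6% of the other probe sets lay under that floor before normalisation, so folds of dim genes understate the change.

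Probe sets were named from a table of the platform's annotation, with symbols checked by Entrez gene ID against the RefSeq genes of GRCm38.p6, in which 34741 of 34945 probe sets with a single gene were found. A further 932 probe sets had several symbols and 9160 had no gene listed. Neither kind was used for named genes. Each of 18193 genes was represented by its probe set with the highest mean over the 12 arrays. A gene was tested if its log2 signal exceeded 6.22, the median of all values (a signal of 74.6), in at least 2 arrays, which left 11696 genes. A gene dim in both vehicle C10 arrays passed only through other arrays, which favours rises among such genes. Probe sets of a gene can disagree: at 48 h, 287 genes had probe sets called in both directions, and of the named genes only Fdft1 did so in a comparison with vehicle C10, at 12 h and 24 h. Genes of multigene families are uncertain, since probes may detect related transcripts.

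Tests used limma (3.58.1) in R (4.3.3), with 1 mean per group fitted to all 12 arrays, empirical Bayes moderation and Benjamini-Hochberg adjustment over the genes tested, two-sided, at adjusted p below 0.05. The 6 groups shared 6 residual degrees of freedom and a prior of 1.53. Comparisons were each time against vehicle C10, HAFTL against vehicle C10, each time against the preceding one, and a moderated F test over the 4 times. For transient courses and the closing tests, 48 h was also compared with 3 h and with 12 h. Errors of log2 changes are standard errors of this fit. Where both arrays of a group lay under the filter level and the other group's mean was above it, the change is a lower bound, given as at least so many fold: the mean of the brighter group against the filter level, with the adjusted p of the fit. Where only 1 of the 2 arrays lay under that level, the fitted change is given, and it is uncertain. This held for Lifr, Pax5 and Mmp9 at 3 h, Vsir from 3 h to 12 h, Lta at 12 h, Ccl2 from 12 h to 24 h, Cdc6 at 24 h, Ms4a6d from 24 h to 48 h, Cox6a2, H2-Aa, Mki67, Mmp11 and Ttll11 at 48 h, and Ifitm3 and Rsad2 in vehicle C10. Groups at the floor have no spread of their own, so the standard errors of their genes rest on the other groups.

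Of a total of 24 gene lists fixed before the data were examined, each was tested with camera at a preset inter-gene correlation of 0.01. Adjustment was over all lists and the 4 times, and over all lists for HAFTL and for 48 h against 3 h. The lists were B lineage, macrophage, granulocyte, myeloid transcription factors, B lineage transcription factors, cell cycle, cell cycle inhibitors, Myc and ribosome biogenesis, cytokines and chemokines, lysosome, adhesion and actin cytoskeleton, MHC class II, interferon response, cholesterol synthesis, immediate early and stress, oestrogen response, stem and progenitor, DNA methylation, dendritic cell, mast cell with basophil and eosinophil, T and NK cell, erythroid, stroma, and housekeeping. Named genes followed a fixed rule: the 10 largest rises and 10 largest falls per time among called genes with both arrays beyond both vehicle arrays, 5 and 5 for the other comparisons, up to 4 members of each list with the largest change at 48 h, and a fixed set of lineage, cell cycle and receptor genes.

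The alternatives tried were the deposited values without quantile normalisation, centring on the array median, no filter and a filter at the 70th percentile, the mean of a gene's probe sets and every probe set on its own, only the groups compared, the replicate number as a block, an intensity trend or a robust prior, a minimum change of 1 on the log2 scale, HAFTL as the control, floors of 1 and 64, a pseudocount of 16, other set tests, and leaving out each array. Scaling to the 12 probe sets of 4 poly-A spike-in transcripts and a floor at the filter level were added after the data were seen. With 1 array left in a group, that array is assumed to vary like the other groups.

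The fit was tested on simulated data for 48 h against vehicle C10, with 10842 genes. It recovered 92% of 100 genes changed by 1 on the log2 scale and 99% of 100 changed by 2, and called 16 of 10609 unchanged genes. The changed genes were drawn only from genes well above the filter level in vehicle C10, and few genes were changed. In the data 62.4% of genes were called at 48 h, so these rates do not cover dim genes or such wide change. Chance values of the covariance for comparisons that share the vehicle arrays came from 100 simulations of unchanged groups, whose correlation is of noise alone. Tables were handled with data.table (1.17.8), and figures drawn with matplotlib (3.10.9) in Python (3.11.15).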

Results

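The data comprised 12 one-colour expression arrays of mouse cell lines, 2 for each of 6 conditions. HAFTL, a fetal liver line transformed with the Ha-ras oncogene, was given beta-estradiol. C10, a line carrying an inducible form of the myeloid transcription factor C/EBPα, was given ethanol as vehicle or beta-estradiol for 3, 12, 24 or 48 h. The series title poses the question of how a B cell line turns into macrophages, and the design names HAFTL as a control. Each array reported 45101 probe sets, and 11696 genes passed the filter on dim signals. The number of arrays limits the precision, and nothing in the labels says that duplicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

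Duplicates lay close together. Over the genes tested, the Pearson correlation between the 2 arrays of a condition ranged from 0.976 at 48 h to 0.980 in vehicle C10, across genes, which are not independent replicates. The first principal component carried 55.5% of the variance and placed vehicle C10, HAFTL and the 3 h arrays together, with 24 h and 48 h far from them. The second component, with 21.9%, set the 3 h and 12 h arrays apart from vehicle C10 and HAFTL.

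**Figure D1:**
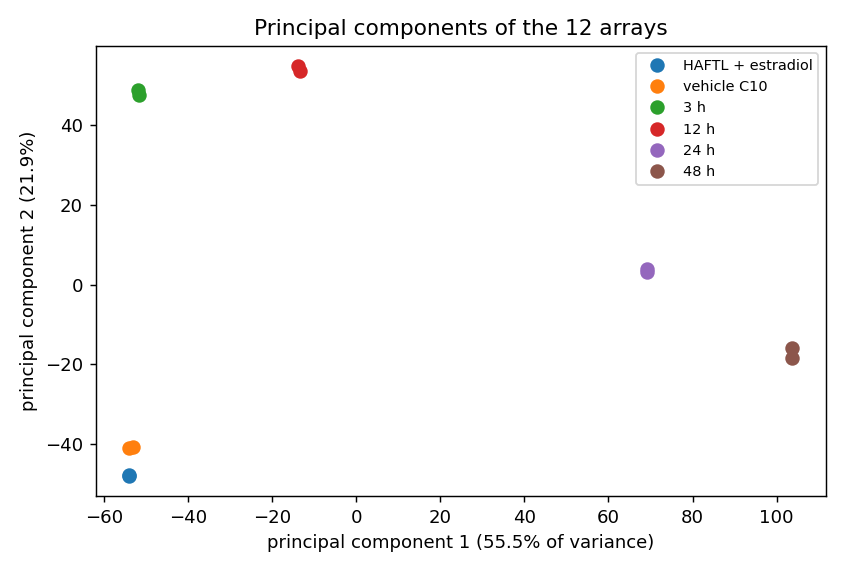
Scores of the 12 arrays on the first 2 principal components of the log2 signals, coloured by condition. On component 1 the 48 h arrays sat at 103.7 and 103.7, the 24 h arrays at 69.2 and 69.2, and the vehicle C10 arrays at -53.1 and -54.0; on component 2 the 12 h arrays sat at 53.6 and 54.8.

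The probe set for Cebpa itself did not track the induced factor. Its signal lay at the floor of 16 in 10 of 12 arrays and reached 34.6 at most, under the filter level of 74.6, so it checks nothing about the introduced construct, whose sequence may lie outside it. Esr1, the oestrogen receptor gene, was higher in vehicle C10 than in HAFTL, where both arrays were under the filter level, by at least 2.79-fold (adjusted p = 9.9e-04). Within C10, Esr1 was lower at 24 h, by at least 2.79-fold (adjusted p = 2.5e-04), and fell by 0.94 ± 0.26 on the log2 scale at 48 h (SE, n = 2 per group). With HAFTL as the control these changes turned to 0.58 and 1.78. Csf3r and Kit did not pass the filter, and Kit exceeded its level in 1 array.

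A large part of the genes tested differed between C10 with estradiol and vehicle C10 at every time (limma with Benjamini-Hochberg adjustment). Against vehicle C10, 2450 genes were higher and 3196 lower at 3 h, 2609 and 3358 at 12 h, 2825 and 3892 at 24 h, and 2831 and 4469 at 48 h. Changes of 2-fold or more numbered 827 up and 1334 down at 3 h, and 1497 up and 2332 down at 48 h. Across the 5 C10 conditions, 8888 genes differed (76.0%, moderated F test), and 5302 under the spike-in scaling described below. The median change over all genes was -0.06 at 3 h and -0.19 at 48 h on the log2 scale. When arrays were scaled to the poly-A spike-in transcripts instead, a choice made after their signals were seen to differ, that median moved to 0.63 at 3 h, 0.65 at 12 h, 0.18 at 24 h and 0.38 at 48 h. Higher genes then made up 84.3%, 86.5%, 64.7% and 69.9% of the calls, against 43.4%, 43.7%, 42.1% and 38.8%. Calls were then 2191 higher and 409 lower at 3 h, 2527 and 396 at 12 h, 1463 and 799 at 24 h, and 2414 and 1041 at 48 h. Fewer genes were thus called in both directions. The balance between higher and lower genes therefore rested on the scaling.

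**Figure D2:**
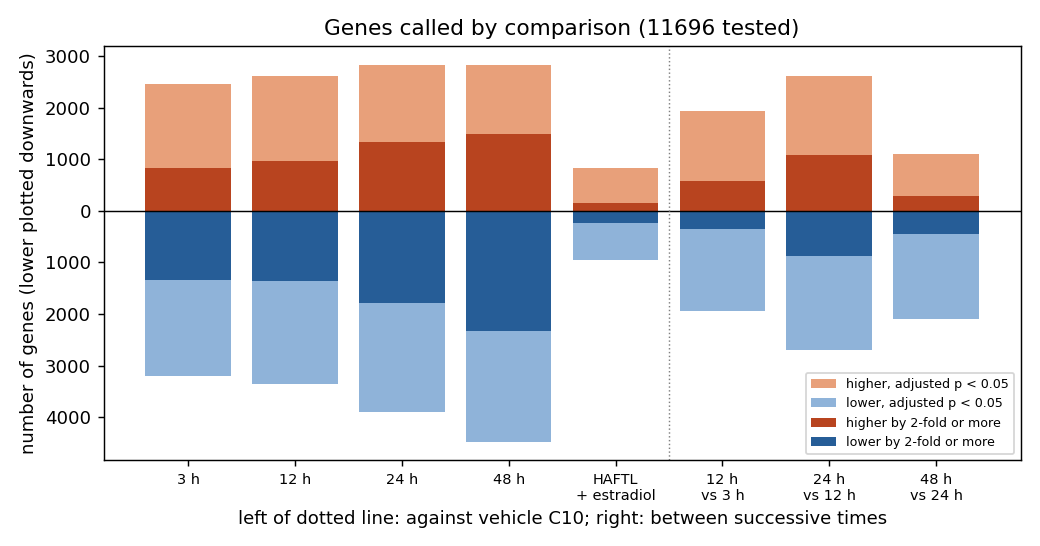
Number of genes called higher (upwards) or lower (downwards) in each comparison, with darker bars for changes of 2-fold or more, out of 11696 tested. HAFTL with estradiol differed from vehicle C10 in 832 higher and 950 lower genes, against 2831 and 4469 at 48 h.

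At 3 h, the recombination activating genes of B and T cell development were among the deepest falls. Rag1 was lower by at least 65.8-fold (adjusted p = 3.2e-06) and Rag2 by at least 17.3-fold (adjusted p = 6.6e-07), and Lta, which encodes lymphotoxin alpha, by at least 113-fold. Cbfa2t3, a transcriptional corepressor, was lower by at least 12.5-fold and Cd248 by at least 7.87-fold. Tmem119 fell by 5.15 ± 0.14 on the log2 scale (SE, n = 2 per group), Enpep by 4.91 ± 0.39, Lifr by 4.88 ± 0.24 and Ddc, which encodes aromatic amino acid decarboxylase, by 4.44 ± 0.10; Gem was lower by at least 18.2-fold. Among the 10 largest fitted rises, Rgcc was higher by at least 27.2-fold and Nfil3, a leucine zipper transcription factor, by at least 9.15-fold. Dgat2, which encodes an enzyme of triglyceride synthesis, rose by 4.93 ± 0.33, the receptor gene Gpr84 by 4.81 ± 0.16 and Hsd11b1, which encodes a glucocorticoid-activating enzyme, by 3.96 ± 0.27. Mmp8, Serpinb2, Ptgs2, Mmp10 and Abtb2 were higher by at least 6.17-fold, 6.70-fold, 5.05-fold, 6.75-fold and 3.79-fold.

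Of 33 B lineage genes tested, 28 fell at 3 h, none rose and 5 did not pass, with a median log2 change of -1.54 (-1.37 with genes under the filter level at their bound). Among 15 B lineage transcription factors, 13 fell and 1, Myb, rose, with a median of -2.45; 12 genes stand on both lists. Spib fell by 3.47 ± 0.15, Bcl11a by 3.44 ± 0.16, Pax5, which maintains B cell identity, by 2.69 ± 0.29 and Ebf1 by 1.68 ± 0.13. Of 37 cell cycle genes, 36 rose and none fell, with a median of 1.68. Cdc6 rose by 2.60 ± 0.59, Ccne2 by 2.35 ± 0.20, Ccna2 by 1.68 ± 0.08 and the proliferation marker Mki67 by 1.06 ± 0.09, while Bub1b had 1.08 ± 0.64 and did not pass. Cholesterol synthesis genes rose in 12 of 14 cases and fell in none, including Idi1 by 2.13 ± 0.09 and Fdft1 by 1.61 ± 0.14. These 4 lists passed the test of the whole list (camera, adjusted p = 1.7e-11, 4.3e-07, 3.4e-18 and 1.1e-07) and held with an estimated correlation. The Actb 5′/3′ signal ratio, a sign of RNA integrity, was 0.610 ± 0.040 in vehicle C10 (mean ± SD, n = 2) and 0.765 ± 0.027 at 3 h, beside these falls and rises, and lay between 0.746 and 0.848 in all 8 arrays of C10 with estradiol. The Gapdh ratio was 1.17 ± 0.03 in vehicle C10 and 1.25 ± 0.09 at 3 h, 1.21 ± 0.06 at 12 h, 1.18 ± 0.00272 at 24 h and 1.16 ± 0.03 at 48 h.

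Macrophage genes were split at 3 h, with 12 of 41 higher and 12 lower. Their median of -0.10 turned to 0.06 with median centring and to 0.46 under spike-in scaling (-0.18 relative to all genes), and the list did not pass (adjusted p = 0.67). Cd14, a receptor for bacterial lipopolysaccharide, was higher by at least 4.08-fold, Mpeg1 by at least 3.40-fold, and Lyz2 rose by 1.49 ± 0.14 (-0.67 with HAFTL as the control), whereas Fcgr1 was lower by at least 3.52-fold and Cd68 fell by 0.73 ± 0.12. Myeloid transcription factors went both ways, 7 up and 7 down of 19, with a median of -0.11 that turned to 0.50 under spike-in scaling (-0.13 relative to all genes): Fos rose by 2.53 ± 0.09 and Spi1, which encodes PU.1, by 0.95 ± 0.09, and Cebpb fell by 1.15 ± 0.16. Immediate early and stress genes rose in 7 of 12 cases, such as Dusp1 by 3.45 ± 0.27 and Ier3 by 3.19 ± 0.12, with none falling (adjusted p = 0.080 with an estimated correlation). Lists whose call was likewise lost were granulocyte genes with 4 up and 1 down of 12 (adjusted p = 0.097 with an estimated correlation), cytokines with 6 up and 1 down of 16 (0.10), MHC class II with 5 down of 9 (0.098) and lysosome with 4 up and 12 down of 26 (0.21). The estimated correlations of the granulocyte, cytokine and MHC class II lists were -0.0027, -0.028 and -0.035. They lay below the preset 0.01, so a higher correlation is not why these 3 calls were lost. The lysosome median of -0.21 turned to 0.50 under spike-in scaling, which is -0.13 relative to all genes. Myc fell by 2.60 ± 0.07, while its list of ribosome biogenesis genes had 5 up and 5 down of 20. Adjusted over the list alone, the counts at 3 h changed only for cholesterol synthesis (14 up), cell cycle inhibitors (5 instead of 4 down) and housekeeping genes (3 instead of 2 up). The second 3 h array had high 18S rRNA control signals. The median change over all genes at 3 h was -0.072 without it and -0.045 without the first 3 h array. Fewer genes were called in both directions without either of them, so that loss was not particular to the second array.

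At 12 h, Hp and Anxa3 were among the largest fitted rises. Hp, which encodes haptoglobin, was higher by at least 79.8-fold (adjusted p = 1.1e-05), Anxa3 by at least 51.8-fold, S100a8 by at least 21.8-fold, Mmp8 by at least 20.4-fold and Camp, a granule antimicrobial peptide gene, by at least 12.4-fold. Serpinb2, Ptgs2, Nfil3 and Abtb2 were higher by at least 24.8-fold, 18.9-fold, 15.2-fold and 12.8-fold, and Gpr84 rose by 6.15 ± 0.16. Ddc was lower by at least 94.6-fold, Enpep by at least 74.9-fold, Rag1 by at least 65.8-fold, Tmem255a by at least 25.1-fold, Cdh17 by at least 24.2-fold, Emid1 by at least 23.0-fold, Haao and Rag2 each by at least 17.3-fold and Cd244a by at least 13.4-fold, and Lta fell by 7.10 ± 0.22.

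The B lineage list had 31 of 33 genes lower at 12 h (median -2.57, and -2.47 with bounds), among them Il7r, the interleukin-7 receptor chain, by -5.10 ± 0.11, and 14 of 15 B lineage transcription factors fell and 1 rose. Macrophage genes were higher in 19 and lower in 10 of 41 cases (median 0.53): Lyz2 rose by 4.50 ± 0.14 and Csf1r, the macrophage growth factor receptor gene, by 1.75 ± 0.16, and Cd68 fell by 1.76 ± 0.12. Cell cycle genes remained above vehicle C10 in 32 of 37 cases with none below (median 1.18), and all 14 cholesterol synthesis genes rose. All 9 MHC class II genes fell (median -2.12), with Cd74 lower by -3.31 ± 0.08, but with HAFTL as the control H2-Aa turned to 1.59 and H2-Eb1 to 0.84. Granulocyte genes rose in 6 of 12 cases, fell in 1 and did not pass in 5. Myeloid transcription factors rose in 12 of 19 and fell in 2, cytokines rose in 7 of 16, adhesion and actin genes rose in 17 and fell in 4 of 25, and immediate early genes rose in 11 of 12. Ribosome biogenesis genes fell in 14 of 20 cases and rose in 1 (adjusted p = 0.11 with an estimated correlation); their median of -0.61 turned to 0.12 under spike-in scaling, or -0.53 relative to all genes. The other 11 lists called at 12 h held with an estimated correlation. Interferon response genes had 4 up and 11 down of 22, and lysosome genes 8 up and 9 down of 26, and neither list passed. Adjusted over the list alone, the counts were 33 up for the cell cycle, 15 down for ribosome biogenesis, 10 and 10 for lysosome, 18 and 5 for adhesion and 5 up for interferon, and the same for the other lists of this paragraph. The Actb 5′/3′ ratio was 0.825 ± 0.033 at 12 h (SD, n = 2).

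At 24 h, inflammatory and macrophage genes were among the largest rises, and the interferon and cell cycle lists had changed. Cd14 was higher by at least 304-fold (adjusted p = 7.7e-06), Il1b, which encodes interleukin-1 beta, by at least 220-fold and Il1rn, its receptor antagonist, by at least 205-fold. Hp, Ifi202b, Mmp13, Camp, Mmp8, Serpinb2 and Mmp12 were higher by at least 243-fold, 199-fold, 152-fold, 107-fold, 93.9-fold, 87.9-fold and 77.3-fold. Rag1, Rag2, Tmem255a, Enpep, Crisp3, Megf10, Mei4, Cd244a and Pfn2 were lower by at least 65.8-fold, 17.3-fold, 25.1-fold, 74.9-fold, 31.1-fold, 30.4-fold, 18.4-fold, 13.4-fold and 48.8-fold, and Il7r fell by 5.97 ± 0.11.

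Interferon response genes rose in 21 of 22 cases at 24 h, with none falling (median 3.08). Rsad2 rose by 5.77 ± 0.32 and Oasl2 by 5.28 ± 0.66. Cell cycle genes were now lower in 32 of 37 cases and higher in 2 (median -1.64), with Cdc6 at -3.20 ± 0.59 and Mki67 at -1.83 ± 0.09. Macrophage genes rose in 35 of 41 cases and fell in 1 (median 3.25, and 2.98 with genes under the filter level at their bound), with Csf1r up by 5.86 ± 0.16. Lysosome genes rose in 20 of 26 cases and fell in 1 (median 1.11). B lineage genes fell in 30 of 33 cases and all 15 B lineage transcription factors fell. Granulocyte genes rose in 8 of 12, myeloid transcription factors rose in 16 and fell in 1 of 19, cytokines rose in 11 of 16, adhesion and actin genes rose in 22 of 25, cholesterol synthesis genes rose in 11 of 14, and ribosome biogenesis genes fell in 17 of 20 and rose in 1. Those 11 lists held with an estimated correlation, as did the cell cycle list. Cell cycle inhibitors, with 7 up and 1 down of 11, were lost with it (adjusted p = 0.23 with an estimated correlation), and immediate early genes, with 9 up of 12, likewise (0.065). Adjusted over the list alone, 34 cell cycle genes were lower and 24 adhesion genes higher, with the same counts for the other lists named here. The Actb 5′/3′ ratio was 0.821 ± 0.024 (SD, n = 2).

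At 48 h, the macrophage programme of the fixed list was higher in 37 of 41 genes and lower in 1, and the B lineage list lower in 30 of 33 and higher in none. Macrophage genes had a median log2 change of 3.94 (3.70 with genes under the filter level at their bound; camera adjusted p = 3.4e-18) and B lineage genes one of -3.38 (-3.06; adjusted p = 8.2e-11). Mmp12, the macrophage elastase gene, was higher by at least 465-fold (adjusted p = 9.4e-08), Cd14 by at least 440-fold, the interferon-inducible gene Ifi202b by at least 454-fold and Mmp13 by at least 368-fold. Il1rn, Usp18, Irf7, Hp and Mmp8 were higher by at least 268-fold, 237-fold, 224-fold, 214-fold and 178-fold, and Ifitm3, with 1 vehicle array just over the filter level and 1 at the floor, had a fitted rise of 9.29 ± 0.69 on the log2 scale (SE, n = 2 per group). Lyz2 rose by 7.51 ± 0.14, Csf1r by 6.36 ± 0.16 and Fcgr1 by 5.59 ± 0.13, and Itgam, the CD11b gene, was higher by at least 8.84-fold.

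Falls at 48 h included B lineage and cell cycle genes. Enpep, Rag1, Cep55, Megf10, Ube2c, Tmem255a, Ikzf3 and Rag2 were lower by at least 74.9-fold, 65.8-fold, 31.2-fold, 30.4-fold, 30.0-fold, 25.1-fold, 19.7-fold and 17.3-fold, and Cox6a2 fell by 6.69 ± 0.48 and Ttll11 by 6.79 (adjusted p = 6.0e-04). Igll1 fell by 3.54 ± 0.07, Vpreb1 by 3.06 ± 0.15, Ebf1 by 2.37 ± 0.13 and Pax5 by 1.28 ± 0.29; Igll1 and Vpreb1 belong to multigene families, so their values are uncertain. All 15 B lineage transcription factors fell (median -3.36). Of 37 cell cycle genes, 34 fell and 2 rose (median -3.37, and -3.10 with bounds), with Mki67 at -6.08 ± 0.09, and Bub1 and Ccna2 lower by at least 22.2-fold and 32.3-fold. Cell cycle inhibitors rose in 8 of 11 cases and fell in 1, with Cdkn1a, the p21 gene, up by 2.78 ± 0.12 and Cdkn2a by 1.74 ± 0.11 (adjusted p = 0.18 with an estimated correlation). Ribosome biogenesis genes fell in 18 of 20 cases (median -2.22), including Polr1b by 3.34 ± 0.19, and Myc fell by 1.77 ± 0.07.

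All 22 interferon response genes rose at 48 h (median 4.63), with Rsad2 up by 8.06 ± 0.32. Myeloid transcription factors rose in 16 of 19 cases and fell in 2: Cebpd rose by 6.45 ± 0.17, Fos by 5.93 ± 0.09, Cebpb by 2.83 ± 0.16 and Spi1 by 1.89 ± 0.09. Cytokine and chemokine genes rose in 14 of 16 cases and fell in 1 (median 4.02, and 2.71 with bounds), granulocyte genes rose in 8 of 12 and fell in 1, lysosome genes rose in 22 of 26 and fell in 2 (median 1.40, and 1.18 with bounds), and adhesion and actin genes rose in 21 of 25 and fell in 1. Among them, Ctsd, a lysosomal protease gene, rose by 3.36 ± 0.08 and Myo1f by 4.92 ± 0.19. Immediate early genes rose in 10 of 12 cases (adjusted p = 0.065 with an estimated correlation), with Dusp1 up by 5.90 ± 0.27. The other 11 lists called at 48 h held with an estimated correlation. Cholesterol synthesis genes rose in 8 and fell in 3 of 14 cases, and the list did not pass (adjusted p = 0.056); Dhcr7 fell by 0.72 ± 0.19. Of the lysosome genes, 5 also stand on the macrophage list. Of 24 listed granulocyte genes, 12 were tested, and S100a9, Elane, Ltf and Ctsg were among those under the filter. Of 23 listed cytokine and chemokine genes, 16 were tested. Counts of these 2 lists therefore leave out members that stayed dim. Adjusted over the list alone, 22 adhesion genes were higher, and the counts of the other lists of this and the preceding accounts of 48 h were the same. The Actb 5′/3′ ratio was 0.797 ± 0.007 (SD, n = 2).

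**Figure D3:**
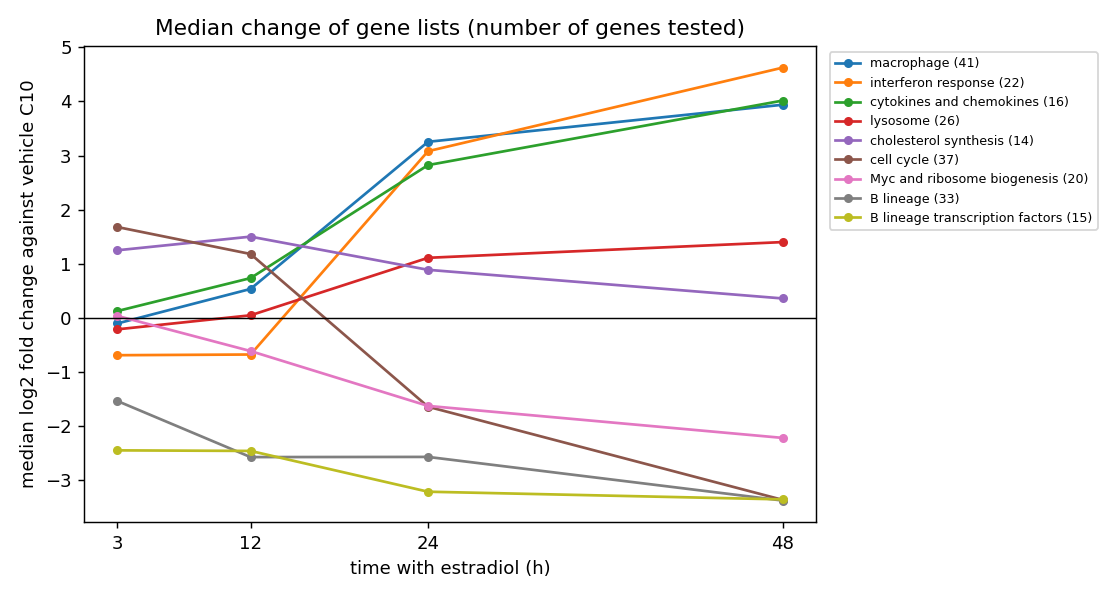
Median log2 fold change of 9 fixed gene lists against vehicle C10, plotted against hours with estradiol; the legend gives the number of genes tested in each. The cell cycle list went from 1.68 at 3 h to -3.37 at 48 h, and the interferon response list from -0.69 to 4.63.

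The remaining lists did not pass the test of the list at 48 h, and of them only MHC class II had passed at an earlier time. MHC class II genes had 2 up and 3 down of 9, with a median of -0.34 that turned to 0.39 under spike-in scaling (0.00534 relative to all genes): Cd74 rose by 1.28 ± 0.08 and H2-DMa by 1.52 ± 0.21, while H2-Aa fell by 4.02 ± 0.28 and H2-Eb1 by 1.82 ± 0.11 (0.54 with HAFTL as the control). Oestrogen response genes had 3 up and 2 down of 9, with Ccnd1 up by 1.28 ± 0.07 and Xbp1 by 1.87 ± 0.10, and Myb down by -3.01 ± 0.08 and Esr1 by -0.94 ± 0.26. DNA methylation genes had 1 up and 3 down of 6 (4 down when adjusted over the list alone), with a median of -0.61 that turned to 0.18 under that scaling (-0.20 relative to all genes): Tet2, which oxidises methylcytosine, rose by 2.20 ± 0.11, and Dnmt3b fell by 2.68 ± 0.12 and Uhrf1 by 2.92 ± 0.23. Markers of other cells were mostly under the filter. Stem and progenitor genes had 1 higher of 6 (Procr, at least 2.20-fold), dendritic cell genes 1 higher and 1 lower of 5 (Itgax, at least 4.65-fold, and Ccr7, at least 1.86-fold), T and NK cell genes 2 lower of 6 (Cd2 by -3.02 ± 0.10 and Cd5 by -1.94 ± 0.14, which turned to 0.99 with HAFTL as the control) and stroma genes 1 higher of 4 (Fn1, at least 22.4-fold), where the medians of the dendritic cell, erythroid and stroma lists, -0.06, -0.08 and -0.30, turned to 0.64, 0.40 and 0.29 under spike-in scaling (0.25, 0.0129 and -0.10 relative to all genes). Neither of 2 mast cell genes nor of 2 erythroid genes passed, and Flt3 had 0.21 ± 0.73. Of 8 housekeeping genes, 3 rose and 3 fell, with B2m up by 0.65 ± 0.07 and Hprt down by -0.95 ± 0.06. Sdha, at -0.51 ± 0.08, turned to 0.0624 under spike-in scaling, and Tbp, lower with adjusted p = 2.4e-04, turned to 0.14 with the mean of all probe sets. The median, mean and test of a list differed in sign for 20 of 120 pairs of list and comparison, none of them called. These were the macrophage, myeloid transcription factor, ribosome biogenesis, oestrogen response and stem lists at 3 h, oestrogen response and erythroid at 12 h, and oestrogen response, stem and housekeeping at 24 h. At 48 h they were MHC class II, oestrogen response, erythroid, stroma and housekeeping, and in HAFTL B lineage, granulocyte, myeloid transcription factors, immediate early and stem.

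**Figure D4:**
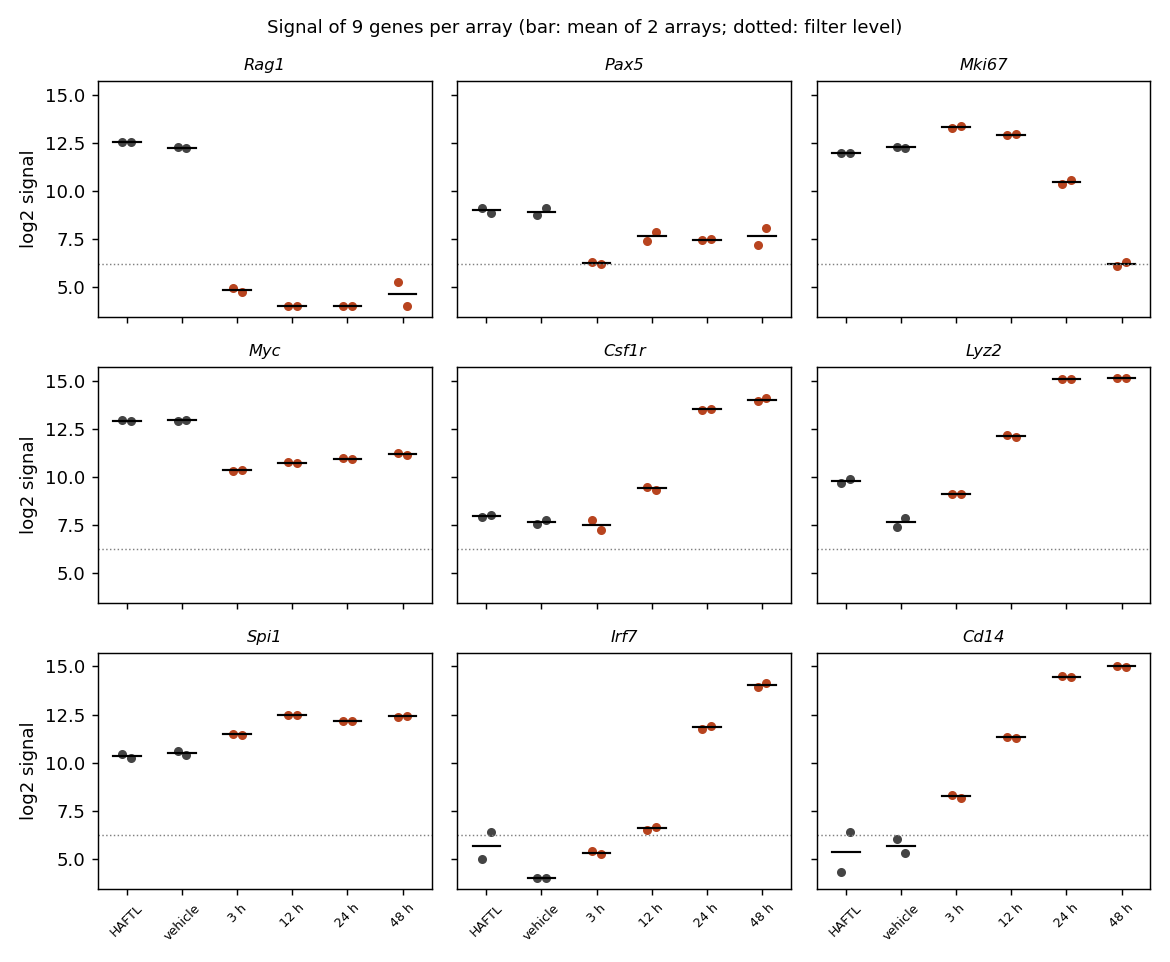
Log2 signal of 9 genes in each of the 12 arrays by condition (points), with the mean of 2 arrays (bar) and the filter level of 6.22 (dotted line). Rag1 lay under that level in all 8 arrays of C10 with estradiol, and Mki67 was above vehicle C10 at 3 h by 1.06 and below it at 48 h, at -6.08.

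HAFTL with estradiol was set against vehicle C10 to see how a line without the inducible factor compares. The lines differed in 832 higher and 950 lower genes, and 162 and 238 by 2-fold or more. Spike-in scaling left 69 and 61, median centring gave 406 higher and the mean of probe sets 609 lower. Dntt, which encodes terminal deoxynucleotidyl transferase, was higher in HAFTL by 5.78 ± 0.46 (SE, n = 2 per group), and Sh3gl3, Kcnn4 and Tle5 by at least 9.77-fold, 5.19-fold and 4.86-fold. Atp1b1, Crisp3, Nedd4l and Dock8 were lower by at least 33.1-fold, 31.1-fold, 8.83-fold and 5.68-fold, and Enpep fell by 4.89 ± 0.39. Most lineage genes did not pass: 26 of 33 B lineage genes (3 up, 4 down), 29 of 41 macrophage genes (6 up, 6 down) and all 12 granulocyte genes. Lyz2 was higher in HAFTL by 2.16 ± 0.14, and H2-Aa was lower by -3.60 ± 0.28. Cholesterol synthesis genes were higher in 8 of 14 cases (adjusted p = 0.054 with an estimated correlation), MHC class II genes lower in 6 and higher in 1 of 9 (0.10), cell cycle genes lower in 5 and higher in 1 of 37 (0.25) and cytokines lower in 4 of 16 (0.17), so none of the 4 lists called held with it. Adjusted over the list alone, B lineage counts were 6 up and 5 down, macrophage 7 and 9, cell cycle 1 and 7, MHC class II 2 and 6, and cytokines 0 and 5. B lineage and macrophage medians of 0.06 and 0.09 fell to -0.12 and to 0 with median centring. The Actb 5′/3′ ratio was 0.716 ± 0.035 and the Gapdh ratio 1.32 ± 0.06 in HAFTL (SD, n = 2). The comparison joins the line, the factor and the compound, and the labels do not give the duration of treatment of HAFTL. With only the 2 groups in the fit, the counts dropped to 135 higher and 182 lower, and without any single array of either group to between 325 and 389 higher and between 443 and 536 lower.

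Of the 3 steps between times with estradiol, which differ in length, the one from 12 h to 24 h had the most calls. From 3 h to 12 h, 1944 genes rose and 1937 fell, from 12 h to 24 h 2611 and 2702, and from 24 h to 48 h 1108 and 2095. In the first step Vsir rose by 5.38 ± 0.29, Hp by 4.78 ± 0.49, and S100a8, Apoc1 and Igsf6 were higher by at least 21.8-fold, 10.2-fold and 3.40-fold; Ddc, Emid1, Cd244a, Cr2 and Cdh17 were lower by at least 4.35-fold, 7.12-fold, 3.52-fold, 6.58-fold and 5.97-fold. In the second step the interferon-inducible genes Oasl2, Mx1 and Rtp4 were higher by at least 84.2-fold, 67.9-fold and 40.4-fold, C3ar1 by at least 47.2-fold, and the chemokine gene Ccl2 rose by 6.96 ± 0.48. The cell cycle list had 36 of 37 genes lower in that step and none higher (median -2.54). Cdc6 had a fitted fall of 5.87 ± 0.59, with 1 array at 24 h under the filter level, and Ung, Ccne2, Dscc1 and E2f7 were lower by at least 18.2-fold, 15.9-fold, 11.8-fold and 7.82-fold. In the last step Ms4a6d rose by 6.02 ± 0.19 and Ms4a6b by 4.09 ± 0.75, and Ms4a4c, Fpr2 and Cxcl3 were higher by at least 20.0-fold, 17.5-fold and 9.09-fold; the Ms4a genes form a family, so their values are uncertain. The cell cycle list had 27 of 37 genes lower from 24 h to 48 h, 10 not passing and none higher (median -1.69), and among the largest falls were Ube2c, Cep55, Nek2 and Kif23, lower by at least 21.1-fold, 9.37-fold, 6.20-fold and 5.11-fold and Mki67 by -4.25 ± 0.09. Under spike-in scaling the 3 steps had 282 higher and 141 lower genes, 497 and 1203, and 172 and 131. With only the 2 groups in the fit, the first step had 1252 and 1193, and 1285 were lower in it without the first 12 h array. The last step had 456 higher and 655 lower genes with only its 2 groups in the fit. Fewer genes were called higher in it also without either 24 h array or the second 48 h array.

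Shares of the 48 h change are given without a test between gene groups. Over the 1497 genes higher by 2-fold or more at 48 h, a median of 7.68% of the 48 h change was present at 3 h, 35.0% at 12 h and 84.0% at 24 h, and over the 2332 lower genes 16.8%, 39.5% and 74.3%. For the 29 B lineage genes among them the shares were 54.5%, 90.8% and 84.4%, and for 36 macrophage genes -0.67%, 21.9% and 76.2%; the 3 h median of the whole macrophage list turned from -0.10 to 0.46 under spike-in scaling. Interferon response genes (21) had -10.5%, -9.94% and 72.5%. These genes were chosen on their 48 h values and share the vehicle arrays with them. Falling genes cannot go below the floor, as with Rag2, which lay at the floor at 3 h, 12 h and 48 h. Rising genes were limited in another way: in those at the floor in vehicle C10, such as Mmp12, any rise below the floor is not seen. Whether the brightest signals level off was not tested. Shares of falling and rising genes are therefore not like for like. Some courses were transient: 1943 genes rose at 3 h or 12 h and then fell to 48 h, 1029 of which ended below vehicle C10, and 2012 fell first and then rose, 740 of which ended above it. Under spike-in scaling these numbers were 1137, 281, 283 and 68. Both kinds, and the number of the first that ended below vehicle C10, thus depended on the scaling. The same 3 h or 12 h arrays entered both calls of a transient course, so noise in them can move a gene into either kind. At the main scaling the 2 kinds made up 1943 and 2012 of 11696 genes. The first kind held 35 of 37 cell cycle genes and 13 of 14 cholesterol synthesis genes. The second held 14 of 41 macrophage, 13 of 22 interferon response, 12 of 26 lysosome and 6 of 9 MHC class II genes. Under spike-in scaling the first kind held 34 of 37 cell cycle genes, and the other lists were not counted.

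Calls at 3 h and 48 h overlapped in part. Of the genes tested, 903 were higher at both times and 1739 lower at both, where independent lists would share 593 and 1221, while 956 were higher at 3 h but lower at 48 h and 677 the reverse, where independent lists would share 936 and 774. The log2 changes correlated across genes with r = 0.230 and a covariance of 0.322. Simulated unchanged groups that shared a vehicle group gave 0.501 and 0.050. Their r is of noise alone, so only the covariance can be set beside the observed one. With no change simulated, hardly any gene can be called, so their 0 shared calls give no chance level for the overlap. Against HAFTL as the control at 48 h, which shares no array with the 3 h comparison, 793 and 1636 genes were shared, where independent lists would share 593 and 1225, with r = 0.155 and a covariance of 0.219 (simulated 0.00113 and 0.00011). There 1017 genes were higher at 3 h but lower at 48 h and 768 the reverse, where independent lists would share 939 and 774. Changes at 24 h and 48 h had r = 0.904 and a covariance of 1.74 (simulated 0.499 and 0.049), and 2335 higher and 3455 lower genes in common, against 684 and 1487 for independent lists. Part of the excess with vehicle C10 may come from the shared arrays. With 1 vehicle array for 3 h and the other for 48 h, chosen after the overlap was seen, 684 and 710 genes were higher at both times and 1289 and 1317 lower in the 2 ways of splitting, where independent lists would share 443 and 438, and 858 and 868. The covariances were then 0.264 and 0.274. Genes higher at 3 h but lower at 48 h numbered 723 and 713, against 672 and 684 for independent lists. The reverse held for 563 and 521, against 565 and 557.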

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

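The tests of scaling, 5′ coverage, HAFTL as an estradiol control, interferon transcripts and both spike-in explanations were chosen or completed after values they use were seen.

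The cell cycle list moved in opposite directions at 3 h and 48 h, with a median log2 change from 3 h to 48 h of -5.08 (camera adjusted p = 8.0e-17, and 0.0021 with an estimated correlation). Between-array scaling is argued against for the early rise, since the lowest median at 3 h over 4 scalings was 1.68. A difference in 5′ coverage of the vehicle arrays cannot be told apart from other causes of the early rise. The list lay at -1.64 at 24 h, where the Actb 5′/3′ ratio was 0.821 against 0.765 at 3 h. Such a difference would shift all times alike against vehicle C10, and a later fall could lie on top of it. The change from 3 h to 48 h compares no vehicle array, so that difference is argued against as its cause. Estradiol acting without the inducible factor cannot be told apart from other causes: the list had a median of -0.24 in HAFTL with estradiol against vehicle C10, but the labels do not give the duration of that treatment. Activity of the induced factor and a change of medium or density with treatment, both untested, stay open as hypotheses.

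Interferon response genes were higher at 24 h and 48 h. Scaling is argued against, since the lowest median at 24 h over 4 scalings was 3.04. If the cells made interferon, its transcripts might be seen, but 0 of 10 interferon probe sets were above the filter level in both arrays at 12 h or 24 h and in no vehicle array, which excludes nothing, since few transcripts may be enough and only 3 of the 10 were above that level in any array. The probe set of Ifnb1 had a mean signal of 46.5 in vehicle C10, 76.6 at 24 h and 232 at 48 h. Interferon made by the cells therefore cannot be told apart from other causes, and a part of the differentiation programme stays open as a hypothesis.

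Poly-A spike-in transcripts had lower signals at 3 h and 12 h, from 181 to 240 in 4 arrays, than in vehicle C10 and HAFTL, from 291 to 389 in 4 arrays, a difference of -0.72 on the log2 scale. The signals were 250 and 314 at 24 h and 335 and 169 at 48 h, so low signals were not confined to 3 h and 12 h. Hybridisation or scanning is argued against, since the hybridisation spike-ins differed by -0.10. More mRNA per input RNA cannot be told apart from a varying spike amount, since duplicates lay up to 0.99 apart, at 48 h. No other explanation was tested.

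The lysosome list had a median change of 1.66 from 3 h to 48 h (camera adjusted p = 1.7e-10, and 0.0088 with an estimated correlation). Its median of -0.21 below vehicle C10 at 3 h was not past the threshold with an estimated correlation (adjusted p = 0.21) and turned to 0.50 under spike-in scaling (-0.13 relative to all genes). The 18S rRNA control probe sets, outside the comparisons, had a geometric mean signal of 4964 in the second 3 h array and 853 in the second 12 h array, above the highest of the vehicle C10 and HAFTL arrays, 824. Among 9160 probe sets with no gene listed, 3977 passed the filter and 1267 were higher and 531 lower at 48 h than in vehicle C10, with changes up to 8.54 ± 0.29 and down to -7.18 ± 0.40 (log2, SE, n = 2 per group).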

How the results depend on the processing

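The spike-in scaling and the floor at the filter level were chosen after the data were seen; all other settings before. Over 19 main results and 545 alternative values, 493 stayed within 1.5 times the main count or, for lists, on the same side of the threshold. The macrophage and B lineage medians at 48 h kept their sign and call throughout, from 3.70 to 4.49 and from -3.54 to -2.55. Among 585 named gene comparisons and 16114 alternatives, 15520 kept their status as called or not called, 356 lost the call, 212 gained it and 26 reversed. Direction was compared only for those called in the main fit, so others may have changed sign. Part of this agreement was fixed by construction. The filters, trend, robust prior, replicate block and fits of only the groups compared leave a gene's change as it is. Leaving out an array of another group does so too. With every probe set tested, the brightest of a gene was read, which is that of the main fit. The totals are therefore no measure of how firm the calls are.

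A minimum change of 1 on the log2 scale, which by construction leaves fewer genes, gave 827 higher and 1334 lower at 3 h, 960 and 1358 at 12 h, 1340 and 1779 at 24 h, 1497 and 2332 at 48 h, 162 and 238 for HAFTL, 585 and 347 from 3 h to 12 h, 1080 and 881 from 12 h to 24 h, 279 and 450 from 24 h to 48 h, and 5183 in the F test. Spike-in scaling, whose factors differ between duplicates by up to 0.99 log2, gave 409 lower at 3 h, 396 lower at 12 h, 1463 higher and 799 lower at 24 h, 1041 lower at 48 h, 69 and 61 for HAFTL, 282 and 141, 497 and 1203, and 172 and 131 for the 3 steps, and 5302 in the F test. With only the groups compared, which leaves fewer samples, HAFTL had 135 and 182, the first step 1252 and 1193 and the last step 456 and 655. Median centring gave 406 higher in HAFTL and the mean of probe sets 609 lower; the cause was not tested.

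Without single arrays, HAFTL ranged from 325 to 837 higher and from 443 to 942 lower, the last step from 693 to 1092 higher and from 1271 to 1990 lower, and the first step from 1285 to 2032 lower. The lowest were without a HAFTL array (325 and 389 higher, 530 and 536 lower) or a vehicle C10 array (373 and 379, 444 and 443), without either 24 h array (693 and 710 higher, 1271 lower without the first) or the second 48 h array (718 higher), and without the first 12 h array (1285).

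Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated between -0.03 and 0.04 over 15 pairs of groups. With the replicate block, 2377 genes were higher and 3114 lower at 3 h and 2805 and 4428 at 48 h, and no count moved by over 1.5 times.

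With HAFTL as the control, these log2 changes reversed: Fcgr1 0.69, H2-Aa 1.59, H2-Eb1 0.84 and Klrd1 0.13 at 12 h, Cd5 1.77 and Esr1 0.58 at 24 h, Cd5 0.59, Ctsd -0.0583, Irf7 -0.36, Lyz2 -0.67 and Nop56 0.16 at 3 h, and Cd5 0.99, Esr1 1.78, Fdft1 -0.0393 and H2-Eb1 0.54 at 48 h. Under spike-in scaling, B2m 0.39, Fcgr1 0.28, Pdgfrb 0.0135 and Wdr12 0.24 at 12 h, B2m 0.33, Nop56 0.56 and Polr1b 0.0937 at 3 h and Sdha 0.0624 at 48 h did. With the mean of probe sets, Fdft1 -0.0142 and Sdha 0.11 at 24 h and Tbp 0.14 at 48 h did; the cause was not tested. Signal near the floor limits folds of dim genes, which are bounds only where both arrays of a group lay under the filter level.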

Other observations

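The families below were chosen after the named genes were seen, and the test of the factor's activity before its result, but the use of its members' spread after it.

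Of 11 matrix metalloproteinases tested, 7 were higher at 48 h and 2 lower, against 3 higher and 2 lower at 3 h. Mmp8, Mmp10, Mmp12 and Mmp13 were already among the named rises, so they lend the family no support of their own. Of the others, Mmp9, Mmp14 and Mmp19 were higher at 48 h, Mmp11 and Mmp23 lower, and Mmp17 and Mmp24 not called. Mmp19 was higher by at least 2.49-fold, Mmp14 rose by 2.10 ± 0.27 and Mmp9 by 2.52 ± 0.39 on the log2 scale (SE, n = 2 per group), and Mmp11 fell by 2.30 ± 0.42. Mmp9 had fallen by 1.19 at 3 h. Of 8 S100A calcium-binding protein genes tested, 6 were higher at 48 h and none lower, with S100a4 up by 6.40 ± 0.18, S100a6 by 1.48 ± 0.13 and S100a10 by 1.43 ± 0.11. The 6 include S100a8, already a named rise, and S100a9 was under the filter. S100a6 and S100a10 had fallen by 1.32 and 1.05 at 3 h.

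One hypothesis was that the inducible factor has some activity in C10 without estradiol. If so, the 1916 genes that rose by 2-fold or more from 3 h to 48 h might already lie higher in vehicle C10 than in HAFTL, in arrays not used to choose them. Their median difference exceeded that of all genes by 0.00157 on the log2 scale, and by -0.0015 to 0.0069 over the 4 pairs of arrays. The 2187 genes that fell lay 0.056 to 0.076 above all genes, where the prediction had them below. That set can include genes that first rose with estradiol. Over all sizes of change, 1585 genes were higher at 3 h than in vehicle C10 and then lower from 3 h to 48 h. Changes complete by 3 h drop out of both sets. The direction therefore does not decide the question. A bound set before the result, that both medians lie within 0.1 of all genes or on the other side, was met. That bound took no account of members going both ways. Of the genes that rose, 11.2% were called higher in vehicle C10 and 9.81% lower, against 8.12% and 7.11% of all genes. Of the genes that fell, 11.8% were called higher and 5.30% lower. The quartiles of the genes that rose lay at -0.29 and 0.31 from the median of all genes. HAFTL had itself received estradiol. Activity without estradiol therefore cannot be told apart from other differences between the lines.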
